A study of Homo sapiens with 2 samples.

How the data were processed

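Libraries from HepG2 and HEK293T cells, 1 per line, were made from total RNA with the Illumina TruSeq Stranded Total RNA Gold kit, which depletes ribosomal RNA, per the labels' protocols. The cells had been transfected with 50 µg of P2A-EGFP plasmid per 150 mm plate and sorted for the brightest 5% of GFP signal 36 to 40 h later. HEK293T cells received TransIT-293 in DMEM and HepG2 cells transfeX in EMEM, so medium and reagent differed along with the line. The authors deposited a table of read counts per gene, whole numbers with no normalization, for 26475 gene symbols. Alignment and processing named STAR, GATK 3.8.1 and Picard 2.7 with GRCh38 (hg38), per the submitters' processing notes, which give no roles for these tools. The counting program, its strand setting and the gene annotation are not given in the sources used here. Reads of overlapping or antisense genes are therefore not separated here, and genes with near-identical copies are reported as uncertain. No molecular identifiers are named in the labels, so copies made by PCR are not separated from molecules.

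Each library was assigned to its line from its title in the labels. The labels call both libraries replicate 1, and this number pairs nothing. The HepG2 library held 65283793 counts and the HEK293T library 47583449. Library sizes were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3), 0.828 for HepG2 and 1.21 for HEK293T. Scaled counts are given as CPM, set to a common library size by these factors. At these sizes 1 count was 0.0185 CPM in the HepG2 library and 0.0174 CPM in the HEK293T library. The floor of 3 counts, which a count of 0 allows, was 0.0555 and 0.0522 CPM. The log2 ratio of HepG2 over HEK293T was taken after adding 0.5 to each count. The added 0.5 was itself scaled by each library's TMM-scaled size over the mean of both, so that equal rates give a ratio of 1. Folds are ratios of scaled counts with a 95% exact Clopper-Pearson interval of the share of HepG2 counts in the sum of both. A fold against a count of 0 was computed against the floor and is given as a lower bound. A gene was measured at 1 CPM or more in either library, and a difference of 4-fold (2 on the log2 scale) was the rule of size. No dispersion can be estimated from 1 library per group, so no test was run and no p-value is given.

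Before the data were examined, 37 gene lists were fixed for liver, kidney, neuronal, adrenal, epithelial, mesenchymal, immune, endothelial, erythroid, deaminase, repair, stress, signalling, metabolic and histone genes. Each list's median ratio was set beside the medians of 10000 random lists of the same size matched on mean log2 CPM in 20 bins. The percentile describes these libraries, and some genes stand in more than 1 list. Gene names in 6 list entries were replaced by older symbols. The list of mitochondrially encoded genes was not analysed here, and 36 lists had measured members. Medians and 4-fold counts of a list cover its measured members only, which leaves out genes low in both libraries. Genes were named by a rule fixed in advance. It takes the 10 most abundant genes at least 4-fold higher in each library. Of each list it takes the 3 most abundant members, the 2 farthest towards HepG2 and the 2 farthest towards HEK293T. It also takes every member of the cytidine deaminase, adenosine deaminase and base excision repair lists. Y-linked genes are not named, and some genes that the rule takes and 1 list are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Gene positions are from GENCODE 29 on GRCh38, matched for 23851 symbols directly and 714 through synonyms. Of the measured genes, 14407 had a chromosome and 360 did not. Chromosome medians were compared with random gene sets of the same size, matched in the same way on mean log2 CPM in 20 bins. Class shares were given exact binomial intervals.

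The computation was checked on simulated data for the HepG2 against HEK293T comparison. Poisson counts were drawn from the mean profile of both libraries at their real total counts. All 200 genes changed by known folds, each larger than the 4-fold rule, were called, 50 of 50 at each fold size. Of 13998 unchanged genes, 0 were called, and the intervals covered the true ratio for 95.5% of them. The simulated counts held counting error alone, so this check says nothing of the spread between real libraries. Both simulated libraries also shared 1 profile apart from the changed genes, so the check does not test scaling across libraries of differing composition. Alternatives fixed in advance were total counts, DESeq2 1.42.0 size factors, upper quartile factors, the HepG2 library thinned to the HEK293T total, small RNA genes left out before scaling, minimums of 10 CPM or of 1 count, 5 counts added in place of 0.5, the lower interval bound as the 4-fold rule, and class shares without the 100 most abundant genes. Totals without the 100 most abundant genes, protein-coding genes alone and a floor of 10 counts were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.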

Results

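RNA-seq read counts per gene were analysed for 2 libraries, 1 from HepG2, a human liver carcinoma line, and 1 from HEK293T, a human embryonic kidney line that carries the SV40 large T antigen. Cells of each line had received a plasmid encoding EGFP behind a self-cleaving P2A peptide, with no guide RNA. The brightest 5% of GFP-positive cells were collected by sorting 36 to 40 h after transfection. This plasmid is the control of a study of RNA editing by DNA base editors, which fuse a deaminase to a CRISPR-guided protein. Total RNA depleted of ribosomal RNA was sequenced with a stranded kit. The HepG2 library held 65283793 counts, with at least 1 count for 20094 genes, and the HEK293T library held 47583449 counts and 21929 genes. With 1 library per line, no difference below has a replicate check and no p-value is given. Ranges in parentheses after a fold are 95% exact intervals of the count ratio, and they cover counting error only. The lines were also grown in different media and transfected with different reagents, so the comparison is between these libraries and not between the lines in general.

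The comparison asked how the transcriptomes of the 2 control libraries differed, since the base editor libraries of each line are read against such controls. Genes of secreted liver proteins were among the most abundant of the HepG2 library. APOB, the main protein of low-density lipoprotein (chromosome 2, 21001429 to 21044073 in GRCh38), had 1143616 and 49 counts in the HepG2 and HEK293T libraries, the order kept for all pairs of counts, a 24801-fold (18759.5 to 33524) difference. ALB, serum albumin (chromosome 4, 73397114 to 73421412), had 967203 and 15 counts, a 68519.9-fold (41543 to 122425) difference. Its neighbour AFP, the fetal counterpart of albumin (chromosome 4, 73431138 to 73456174), had 479332 and 4 counts, a 127340.0-fold (49734 to 467364) difference. Carry-over of HepG2 reads, at most 0.00214% by the upper limit of the AFP counts, could give some or all of such few HEK293T counts. Folds of genes this abundant in the HepG2 library may therefore be too low, and their intervals do not cover this. The other genes among the 10 most abundant of those at least 4-fold higher in the HepG2 library were FN1, TF, FTL, SERPINA1, AHSG, LYZ and PEG10. They encode fibronectin, transferrin, ferritin light chain, alpha-1 antitrypsin, fetuin-A, lysozyme and an imprinted retrotransposon-derived protein. FN1 was 160.3-fold (156 to 165) and FTL 37.9-fold (37.1 to 38.7) higher, while the folds of the other 5 ran from 3932-fold for PEG10 to 44996-fold for LYZ.

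On the HEK293T side, the leading gene was AMOT, a scaffold protein that binds YAP in the Hippo pathway (chromosome X, 112774503 to 112840815), with 6 and 97319 counts, a 15264-fold (7012 to 41593) difference. LDHB, the B subunit of lactate dehydrogenase (chromosome 12, 21635342 to 21757857), had 7 and 65608 counts, or 8820.0-fold (4281 to 21938) more in the HEK293T library. IRS4, an adaptor of insulin receptor signalling, was 1209.6-fold (877 to 1718) higher there. Smaller differences were found for PLS3, an actin-bundling protein, at 4.69-fold (4.61 to 4.78), for CKB, brain-type creatine kinase, at 4.92-fold (4.79 to 5.06), and for PARP1, a sensor of DNA strand breaks, at 4.10-fold (4.02 to 4.18). The remaining 4 of the 10 genes were the histone genes HIST1H2BJ, HIST1H2BK, HIST2H2BF and HIST1H2AG, higher by 5.63-fold to 27.4-fold. Histone genes are near-identical copies, so how the counting divided reads among them is uncertain.

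Of 14767 genes with at least 1 CPM (count scaled to library size) in either library, 1670 (11.3%) were at least 4-fold higher in the HepG2 library and 2241 (15.2%) in the HEK293T library. The HepG2 library thus held 42.7% of these genes, and 31.0% when libraries were scaled by total counts, with 1265 and 2813 genes. At a minimum of 10 CPM the balance turned, with 1092 genes higher in the HepG2 library and 968 in the HEK293T library. Another 8082 genes (54.7%) differed by less than 2-fold. The log2 CPM of the libraries had a Pearson correlation of 0.70 across genes, which are not independent replicates. A gene counted as present in 1 library alone when it reached 1 CPM there and had at most 3 counts in the other. This held for 293 genes in the HepG2 library and 842 in the HEK293T library, numbers that changed by over 1.5 times with other minimums. Examples were CCL20, a chemokine, with 7336 and 0 counts, and VIM, the intermediate filament protein vimentin, with 0 and 17987 counts.

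**Figure D1:**
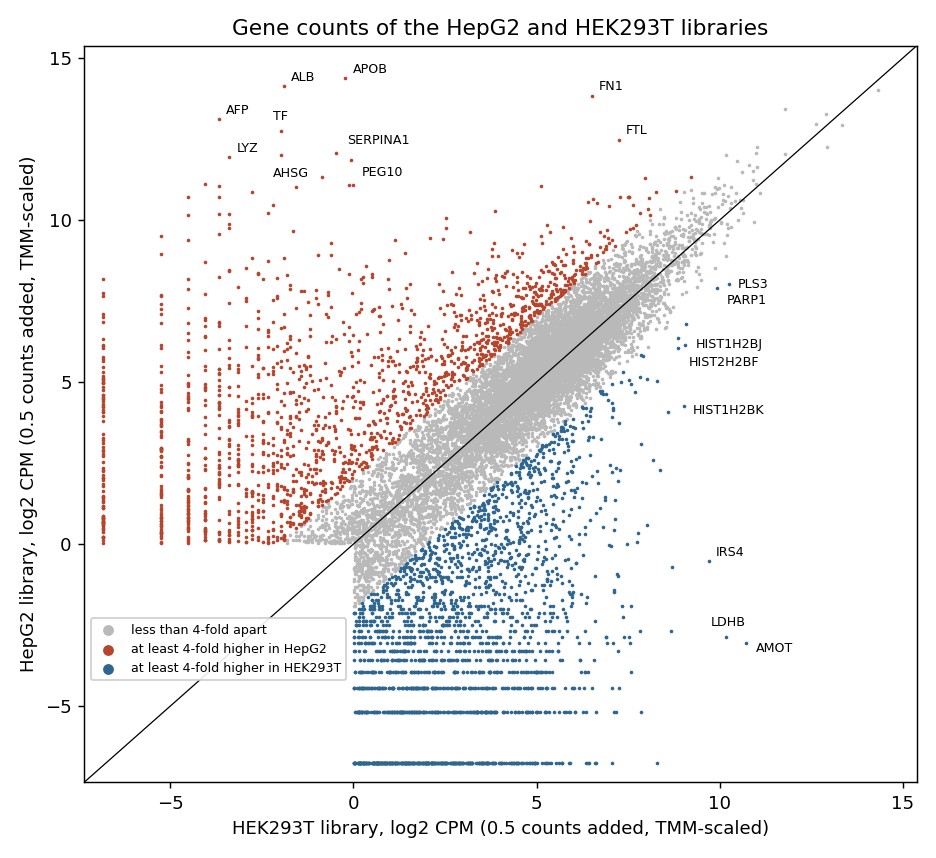
Each point is a gene with at least 1 CPM in either library, with log2 CPM in the HEK293T library on the horizontal axis and in the HepG2 library on the vertical axis (0.5 counts added, Y-linked genes not drawn). Red and blue points were at least 4-fold higher in the HepG2 and HEK293T libraries, and labels mark 18 of the 20 most abundant such genes, from ALB and APOB at the top to AMOT and LDHB at the lower right.

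The medians of the lists of hepatocyte function lay towards HepG2. Of 31 measured plasma protein genes, 30 were at least 4-fold higher there, and the exception, A1BG, was 1.97-fold (1.71 to 2.28) higher. Their median log2 ratio of 12.52 lay above all 10000 random lists matched on expression, and was 11.80 with genes at the floor of 3 counts put at their bound. APOH, a phospholipid-binding plasma protein, had 89962 and 2 counts, a ratio of 47799-fold (13232 to 394698). Among 24 liver-enriched transcription factors, 16 were at least 4-fold higher in the HepG2 library and 2 in the HEK293T library (median 3.46). The nuclear receptor HNF4A had 22468 and 3 counts, and NR1H4, the bile acid receptor, 3859 and 1 count, with a ratio of 4101-fold (736 to 162013). The 2 exceptions were GATA6, 12.5-fold (10.5 to 15.0) higher in the HEK293T library, and the nuclear receptor NR5A2, 4.57-fold (3.48 to 6.08) higher there. Both medians lay above all 10000 random lists.

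The medians of the bile acid, drug-metabolising and gluconeogenesis lists lay in the same direction. In the bile acid list 16 of 23 genes were measured. Of these, 13 were at least 4-fold higher in the HepG2 library and 0 in the HEK293T library (median 4.88). They included CYP27A1, a sterol hydroxylase of bile acid synthesis, at 338-fold (243 to 486), the canalicular exporter ABCC2 at 356-fold (272 to 477), and the transporter subunit SLC51B with 433 and 0 counts, at least 153-fold higher. Of 29 drug-metabolising enzymes, 16 were measured and 13 were at least 4-fold higher in the HepG2 library (median 6.35, 5.85 at the bound). ALDH1A1, a retinaldehyde dehydrogenase, was 162-fold (143 to 184) higher, and the carboxylesterase CES1 had 11190 and 1 count, while EPHX1, microsomal epoxide hydrolase, differed by 1.04-fold (0.965 to 1.11). In gluconeogenesis, amino acid catabolism and urea synthesis 21 of 26 genes were measured. Of these, 12 were at least 4-fold higher in the HepG2 library and 0 in the HEK293T library (median 3.32). HGD and HPD, enzymes of tyrosine breakdown, were 2002-fold (857 to 6166) and 361-fold (259.7 to 519) higher. ASS1, an enzyme of the urea cycle, had 1838 and 1780 counts and OAT, ornithine aminotransferase, 6884 and 10253 counts. These 3 medians also exceeded all 10000 random lists.

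The medians of the complement and iron lists lay towards HepG2 as well. Of 29 complement and acute phase genes 18 were measured, and 15 were at least 4-fold higher in the HepG2 library (median 7.89). Complement component C3, which is also in the plasma list, was 2181-fold (1683 to 2880.2) higher. The acute phase glycoproteins ORM1 and ORM2, near-identical neighbours whose reads may not be separable, had 15575 and 0 counts and 10869 and 1 count. The complement protease C1R and its inhibitor SERPING1 were less than 4-fold apart, at 171 and 298 counts and 65 and 87 counts. In iron handling 9 of 17 genes were at least 4-fold higher in the HepG2 library and 1 in the HEK293T library (median 2.83). Ceruloplasmin, CP, was 6230.4-fold (3482 to 12482) higher and the ferritin receptor NCOA4 7.10-fold (6.96 to 7.25), while BMP6, a signal that raises hepcidin, was 12.0-fold (8.69 to 17.0) higher in the HEK293T library. Both medians lay above all 10000 random lists.

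Oncofetal, Wnt-responsive and NRF2-responsive lists were also shifted towards HepG2. Of 15 measured oncofetal and imprinted genes, 8 were at least 4-fold higher in the HepG2 library (median 3.8, and 0.96 with no filter beyond 1 count). GPC3, a fetal liver proteoglycan, was 60.7-fold (58.0 to 63.4) higher and DLK1, an imprinted Notch-related protein, at least 2474-fold. The imprinted cell cycle inhibitor CDKN1C was at least 73.7-fold higher in the HEK293T library (0 and 235 counts). Among 20 Wnt and beta-catenin targets, 10 were at least 4-fold higher in the HepG2 library and 3 in the HEK293T library (median 1.67). The Wnt inhibitors NOTUM and NKD1 were 952-fold (663 to 1422) and 31.0-fold (29 to 33.2) higher, and the transcription factor SP5 884-fold (517 to 1660.1). LEF1, a partner of beta-catenin, was 34.4-fold (25.5 to 47.8) higher in the HEK293T library. NRF2 targets had 8 of 21 genes at least 4-fold higher in the HepG2 library (median 1.85). NQO1, a quinone reductase, was 152-fold (136 to 169.8) higher and the aldo-keto reductase AKR1B10 at least 1003-fold, whereas ME1, malic enzyme, had 3 and 1818 counts, a ratio of 570.3-fold (195 to 2768) towards HEK293T. The medians exceeded 10000, 9998 and 9998 of 10000 random lists.

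The medians of the patterning and neuronal lists lay towards HEK293T. Of 36 measured HOX genes, which set position along the body axis, 33 were at least 4-fold higher there (median -8.18, -6.30 at the bound). HOXD13 had 2 and 5209 counts, HOXB9 1 and 3821 counts and HOXD10 0 and 1608 counts. HOXD1 went the other way, 8.86-fold (6.67 to 12.0) higher in the HepG2 library, and HOXA3 had 288 and 309 counts. Of 19 embryonic kidney and intermediate mesoderm factors 15 were measured. Of these, 12 were at least 4-fold higher in the HEK293T library (median -7.41, -5.10 at the bound). CITED1 and SIX2, both markers of nephron progenitors, had 2 and 8808 counts and 0 and 839 counts. PAX8, a kidney and thyroid factor, was the 1 gene at least 4-fold higher in the HepG2 library, at 340 and 3 counts. In the neuronal and neuroendocrine list 21 of 31 genes were measured. Of these, 14 were at least 4-fold higher in the HEK293T library and 2 in the HepG2 library (median -3.86, and -6.85 at a minimum of 10 CPM). The neurofilament genes NEFM and NEFL were 206-fold (159 to 273) and 621-fold (370.2 to 1137) higher in the HEK293T library, while the neuronal tubulin TUBB3 was 41.2-fold (36.8 to 46.2) higher in the HepG2 library. All 10000 random lists lay above each of these 3 medians.

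Adrenal, epithelial and mesenchymal lists separated the libraries too. In the adrenal cortex list, 7 of 14 genes were measured, and 5 were at least 4-fold higher in the HepG2 library (median 2.49, above 9986 of 10000 random lists). The steroidogenic factor NR5A1 was 263-fold (162 to 460.4) higher there and the sulfotransferase SULT2A1, which is also a liver enzyme, 152-fold (119 to 196). NR0B1, a repressor partner of NR5A1, had 0 and 84 counts. Of 21 epithelial genes 15 were measured, and 12 were at least 4-fold higher in the HepG2 library (median 3.41, above all 10000 random lists). The keratin genes KRT8 and KRT18 were 85.7-fold (80.1 to 91.9) and 19-fold (18.2 to 19.8) higher, while CGN, the tight junction protein cingulin, was 17.0-fold (13.8 to 21.0) higher in the HEK293T library. Of 19 mesenchymal genes, 11 were at least 4-fold higher in the HEK293T library and 3 in the HepG2 library (median -3.12, below all 10000 random lists). VIM was at least 5642-fold and the transcription factor TWIST1 at least 152-fold higher in the HEK293T library. FN1 and the actin-binding protein TAGLN went towards HepG2, TAGLN by 50.9-fold (37.9 to 70.0), and CDH2, N-cadherin, had 9627 and 7471 counts.

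**Figure D2:**
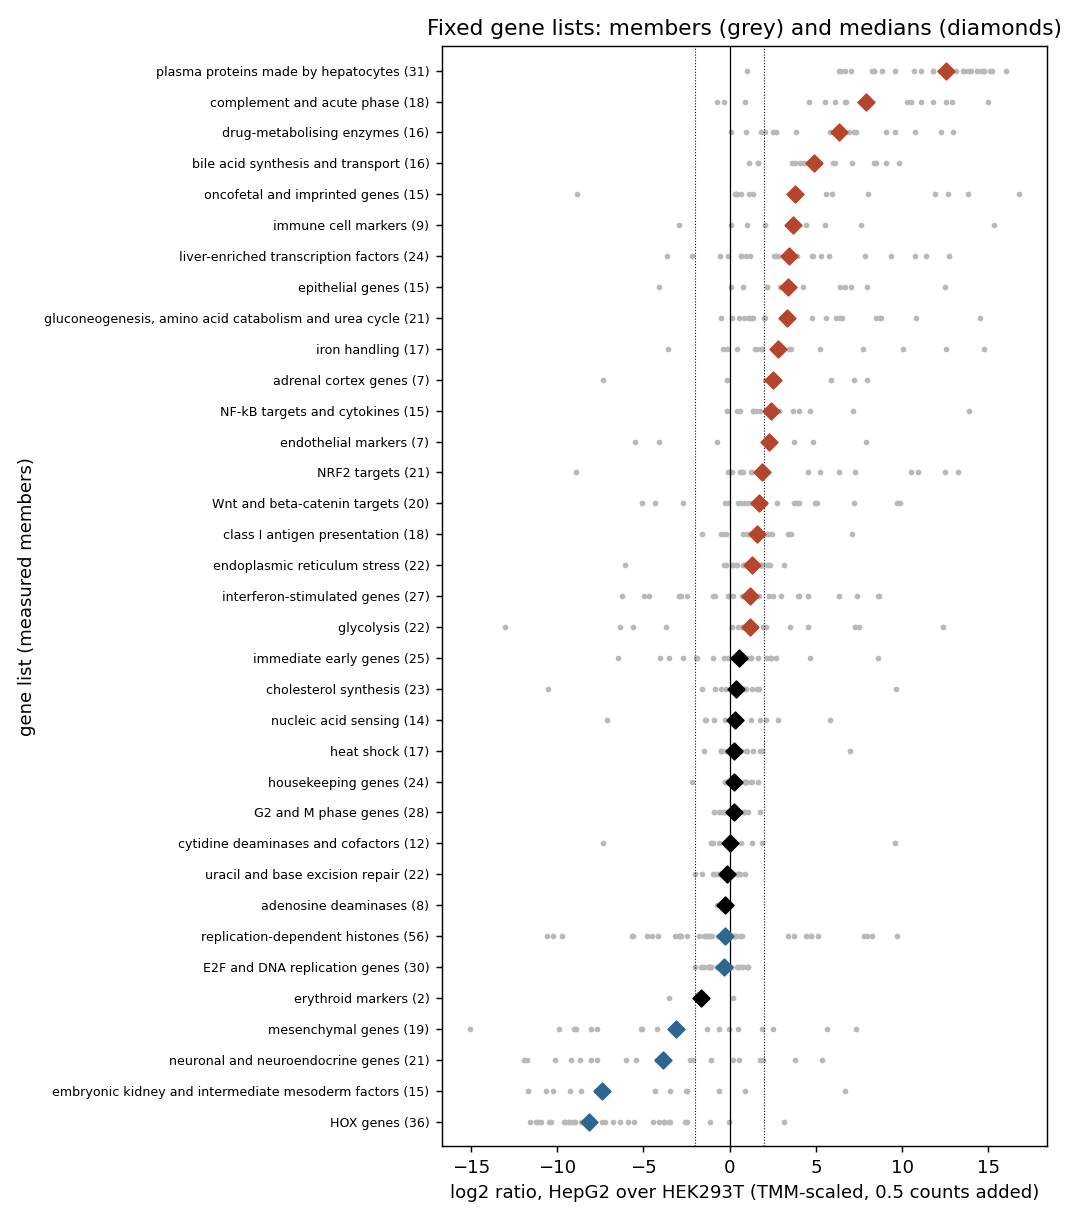
Log2 ratios of HepG2 over HEK293T on the horizontal axis for gene lists with measured members, each named on the vertical axis with the number measured. Grey points are genes, diamonds are list medians, dotted lines mark 4-fold, and red or blue diamonds lie above the 97.5th or below the 2.5th percentile of random lists, from 12.52 for plasma proteins to -8.18 for HOX genes.

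Because base editors carry a deaminase, the lines' own deaminase and repair genes were compared gene by gene. Cytidine deaminases and their cofactors showed no common direction, with a median of 0.01, above 62.8% of random lists. The clear difference was A1CF, the RNA-binding partner with which APOBEC1 edits APOB transcripts, at 12710 and 17 counts, or 794-fold (496 to 1364) higher in the HepG2 library. APOBEC1 itself had 0 and 1 count, both under the floor, and APOBEC3A had 0 counts in both libraries. The antiviral deaminase genes APOBEC3B and APOBEC3C had 207 and 217 counts and 955 and 1108 counts, and the interval of the APOBEC3B ratio, 1.01-fold (0.834 to 1.23), included 1. APOBEC3F was 2.09-fold (1.68 to 2.61) higher in the HEK293T library and APOBEC3D 2.00-fold (1.29 to 3.18), while APOBEC3G was 1.59-fold (1.13 to 2.26) and APOBEC2 2.51-fold (1.55 to 4.18) higher in the HepG2 library. APOBEC3H had 2 and 14 counts and APOBEC4 19 and 14 counts, under 1 CPM in both. The other APOBEC1 cofactors RBM47 and SYNCRIP had 390 and 626 counts and 14632 and 15497 counts. DCTD, dCMP deaminase, was 3.64-fold (3.44 to 3.85) higher in the HepG2 library, and CDA, cytidine deaminase, and CDADC1 had 46 and 55 counts and 407 and 404 counts. APOBEC3 genes are close paralogs, so the division of reads among them is uncertain.

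None of 8 measured adenosine deaminase genes passed 4-fold, and their median was -0.27, above 25.3% of random lists. ADAR, the main editor of double-stranded RNA, had 15168 and 22203 counts and was 1.38-fold (1.35 to 1.41) higher in the HEK293T library. ADARB1, the other catalytically active ADAR, had 886 and 956 counts, with a ratio of 1.02-fold (0.926 to 1.11). The tRNA adenosine deaminase genes ADAT1, ADAT2 and ADAT3 had 1358 and 1447 counts, 1349 and 1679 counts and 141 and 225 counts. For the purine enzymes, ADA had 752 and 998 counts, AMPD2 3587 and 3889 counts and AMPD3 41 and 74 counts. ADARB2, ADAD1, ADAD2, CECR1 and AMPD1 had at most 5 counts in either library.

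Base excision repair genes were mostly close in level. Of 22 genes, 21 were less than 4-fold apart and PARP1, named above, was the exception. The median was -0.17, above 12.6% of random lists. UNG, which removes uracil from DNA, had 7813 and 5871 counts, a log2 ratio of 0.50. The thymine and uracil glycosylase TDG was 3.01-fold (2.82 to 3.21) higher in the HEK293T library. Among the other glycosylase genes, SMUG1 had 1285 and 1577 counts, MBD4 1633 and 1982 counts, NEIL1 133 and 261 counts, NEIL2 1592 and 915 counts and NEIL3 814 and 1702 counts. MPG, which removes alkylated adenine, had 2317 and 1629 counts, OGG1 929 and 873 counts, MUTYH 413 and 446 counts and NTHL1 2166 and 1684 counts. The abasic endonuclease genes APEX1 and APEX2 had 6750 and 8302 counts and 1329 and 2347 counts. Gap-filling and ligation genes were POLB with 1500 and 1358 counts, POLL with 852 and 1356 counts, LIG1 with 3625 and 2712 counts, LIG3 with 3939 and 4620 counts, XRCC1 with 1498 and 1729 counts and FEN1 with 6259 and 9891 counts. PARP2, a paralog of PARP1, had 2283 and 2295 counts. With total counts as the scale, all ratios moved by -0.54 on the log2 scale towards HEK293T, and TDG passed 4-fold as well as PARP1. The direction of UNG and of other genes with positive log2 ratios below the size of this shift turned.

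**Figure D3:**
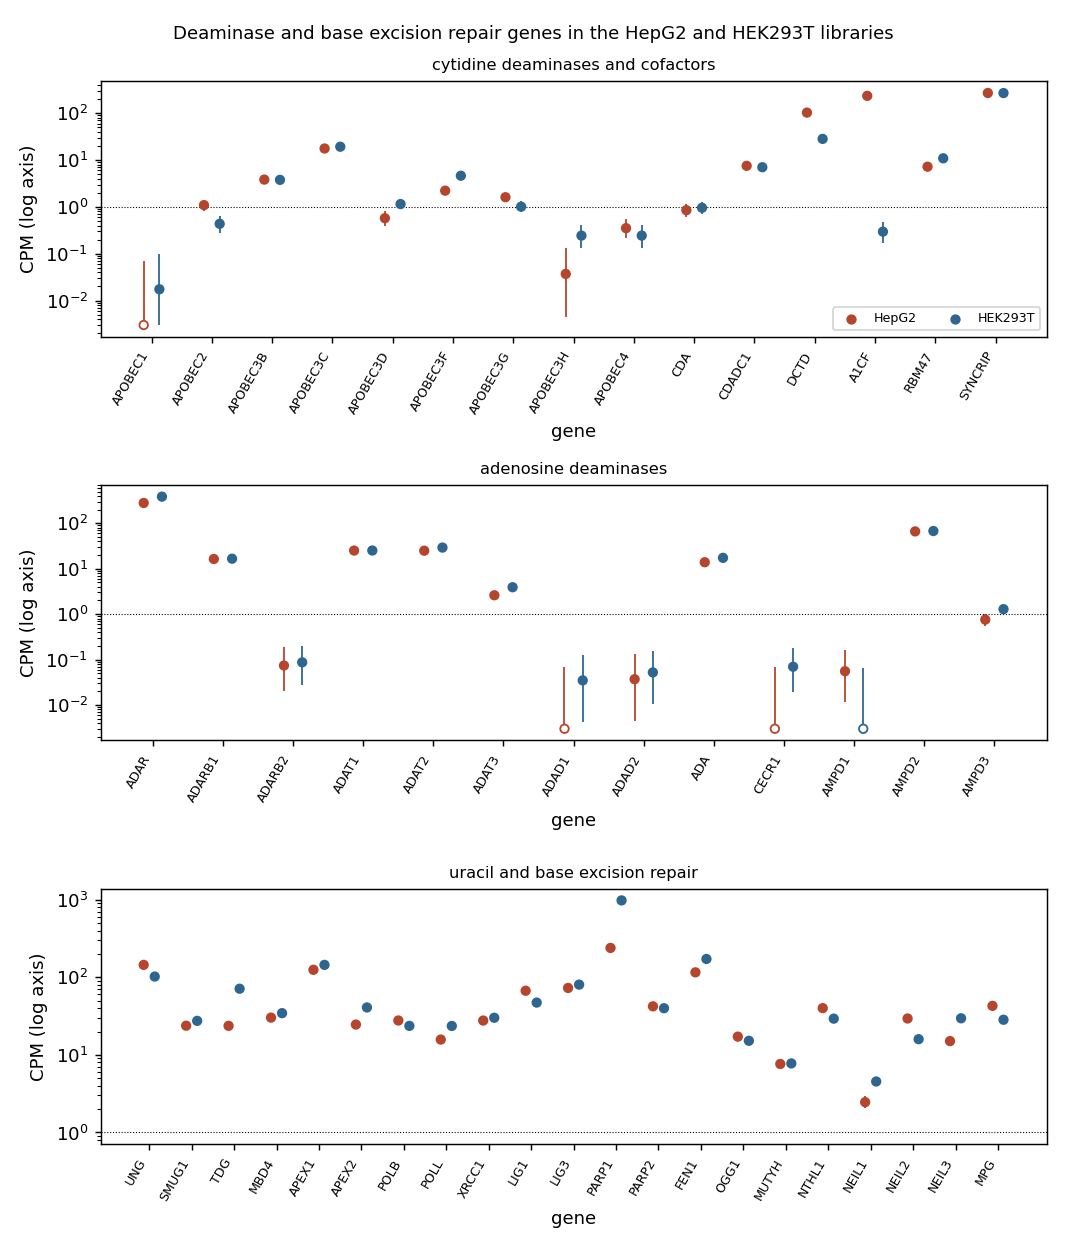
TMM-scaled CPM, on a log axis, of each gene named on the horizontal axis in the HepG2 (red) and HEK293T (blue) libraries. Vertical lines are 95% Poisson intervals of the count, open circles at the foot of an axis are 0 counts, dotted lines mark 1 CPM, and A1CF shows the widest separation of the genes with counts in both libraries.

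Few cell cycle genes passed 4-fold. Of 30 E2F and DNA replication genes, 29 were less than 4-fold apart, and their median of -0.31 lay above 4 of 10000 random lists. MCM6, a subunit of the replicative helicase, was 4.03-fold (3.87 to 4.19) higher in the HEK293T library, and POLE, a replicative polymerase, 3.12-fold (3.01 to 3.25). PCNA, the sliding clamp, was 2.11-fold (2.06 to 2.16) higher in the HepG2 library. None of 28 G2 and M phase genes passed 4-fold (median 0.23, above 28.4% of random lists). TOP2A, a topoisomerase of dividing cells, was 2.09-fold (2.06 to 2.12) and the kinase AURKA 3.32-fold (3.22 to 3.42) higher in the HepG2 library, while the proliferation marker MKI67 was 1.91-fold (1.85 to 1.96) higher in the HEK293T library.

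Interferon-stimulated, NF-kB and antigen presentation lists were shifted towards HepG2. Of 27 measured interferon-stimulated genes, 10 were at least 4-fold higher in the HepG2 library and 6 in the HEK293T library (median 1.17, above all 10000 random lists). The antiviral GTPase MX2 was 443-fold (203 to 1208) and the membrane protein IFITM3 23.7-fold (19.7 to 28.6) higher in the HepG2 library, and OAS1, which senses double-stranded RNA, at least 66.6-fold. HERC5, an ISG15 ligase, was 76.7-fold (50.5 to 123) higher in the HEK293T library. In nucleic acid sensing the median was 0.33, above 80.2% of random lists. The RNA sensor IFIH1 was 6.95-fold (5.55 to 8.79) and the adaptor MAVS 2.39-fold (2.32 to 2.47) higher in the HepG2 library, and the DNA sensor IFI16 had 0 and 70 counts. Among NF-kB targets 15 of 28 genes were measured. Of these, 8 were at least 4-fold higher in the HepG2 library and 0 in the HEK293T library (median 2.40, above all 10000 random lists). The chemokine CCL20 was at least 2599-fold higher, the adhesion molecule ICAM1 143-fold (107 to 194) and the NF-kB inhibitor NFKBIA 6.10-fold (5.76 to 6.46). Class I antigen presentation had 6 of 18 genes at least 4-fold higher in the HepG2 library (median 1.57, above 9999 of 10000 random lists). The immunoproteasome subunit PSMB8 was 143-fold (77.6 to 299) higher there, while HLA-B was 1.42-fold (1.34 to 1.49) higher in the HEK293T library. HLA genes are polymorphic paralogs, so their counts are uncertain.

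Stress lists were divided. Endoplasmic reticulum stress genes had a median of 1.32, above 9997 of 10000 random lists, with 4 of 22 at least 4-fold higher in the HepG2 library. TRIB3, a pseudokinase induced by ATF4, was 8.97-fold (8.47 to 9.51) and the disulfide isomerase PDIA6 4.40-fold (4.31 to 4.49) higher there, while CHAC1, which degrades glutathione, had 2 and 175 counts. Heat shock genes had a median of 0.27, above 47.1% of random lists. The mitochondrial chaperonin HSPD1 was 3.60-fold (3.56 to 3.63) higher in the HepG2 library. The inducible pair HSPA1A and HSPA1B, near-identical neighbours, had 4599 and 38 counts and 7666 and 23103 counts, and how reads were divided between them is uncertain. Immediate early genes had 7 of 25 at least 4-fold higher in the HepG2 library and 4 in the HEK293T library (median 0.53, above 96.7% of random lists). DUSP6, a phosphatase of ERK, was 399-fold (276 to 601) higher in the HepG2 library, and DUSP2, a related phosphatase, 96.6-fold (41.1 to 299) higher in the HEK293T library. MYC was 2.06-fold (2.00 to 2.13) higher in the HepG2 library and JUN 1.94-fold (1.88 to 2.01) higher in the HEK293T library.

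In glycolysis, 6 of 22 genes were at least 4-fold higher in the HepG2 library and 4 in the HEK293T library (median 1.16, above 9959 of 10000 random lists). The liver glucose transporter SLC2A2 had 7478 and 1 count, the transporter SLC2A3 was 184-fold (165 to 205) higher in the HepG2 library, and HK1, hexokinase of most tissues, was 82.1-fold (66.9 to 102) higher in the HEK293T library. Cholesterol synthesis genes were centred near the other genes (median 0.35, above 61.5% of random lists). INSIG1, the sterol-regulated anchor of SREBP (chromosome 7, 155297776 to 155310235), had 5 and 8624 counts, or 1623-fold (695 to 5000.1) more in the HEK293T library. Housekeeping genes had a median of 0.23, above 24.9% of random lists, and 23 of 24 were less than 4-fold apart. The translation factor EEF1A1 was 3.13-fold (3.12 to 3.15) and actin, ACTB, 1.84-fold (1.83 to 1.85) higher in the HepG2 library, and HPRT1, a purine salvage enzyme, was 4.52-fold (4.21 to 4.84) higher in the HEK293T library. Scaling by total counts shifted the median of all genes by -0.54 from its value of 0.04, and upper quartile factors by -0.22. Under total counts the medians of the cytidine deaminase, G2 and M phase, nucleic acid sensing, heat shock, immediate early, cholesterol and housekeeping lists turned negative, at -0.53, -0.31, -0.21, -0.27, -0.01, -0.20 and -0.31.

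Markers of other cell types were mostly under 1 CPM. Of 21 immune cell markers 9 were measured, with a median of 3.65, above 9998 of 10000 random lists, that was 0.087 with no filter beyond 1 count. LYZ gave the highest value, and CD74, the class II invariant chain, had 2443 and 55 counts, while LCP1, an actin-bundling protein of blood cells, was 7.77-fold (7.0 to 8.64) higher in the HEK293T library. Of 17 endothelial markers 7 were measured, with a median of 2.28, above 98.8% of random lists, that was -4.10 at a minimum of 10 CPM. PECAM1 and CDH5, endothelial junction proteins, had 285 and 10 counts and 116 and 0 counts, and EGFL7, a secreted vascular protein, 58 and 1066 counts. Of 16 erythroid markers 2 were measured (median -1.65, above 22.6% of random lists). HBB, beta-globin (chromosome 11, 5225464 to 5229395), was abundant in both libraries, with 80125 and 73273 counts, though reads it shares with its paralog HBD make the count uncertain. TAL1, a blood transcription factor, had 15 and 187 counts. The 15 mitochondrially encoded genes on the fixed list were not analysed here.

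Replication-dependent histones took a larger share of counts in the HEK293T library. The 73 histone genes made up 1.59% of HEK293T counts (1.59 to 1.60, exact binomial interval) and 0.898% of HepG2 counts (0.896 to 0.901). Shares in this paragraph are of total counts, while its log2 ratios are TMM-scaled, so the size of a share difference cannot be set against them. Of 56 measured, 10 were at least 4-fold higher in the HepG2 library and 14 in the HEK293T library, and the median of -0.28 lay below all 10000 random lists. HIST1H1B, a linker histone, had 9992 and 12 counts and HIST1H3C 20702 and 72 counts, while HIST1H3A had 7 and 9574 counts and HIST3H2BB 6 and 10833 counts. Summed over all copies, the families were closer than these single genes. Their log2 ratios were -0.33 for H1, -0.40 for H2A, -0.45 for H2B, 0.20 for H3 and -0.21 for H4, and H3 turned negative with total counts. Ribosomal protein genes made up 6.25% of HepG2 and 6.11% of HEK293T counts. Small RNA genes made up 4.10% and 6.69%, and 0.30% and 0.405% with the 100 most abundant genes of either library left out. The 10 most abundant genes held 10.1% of HepG2 counts and 7.98% of HEK293T counts.

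Median ratios also differed by chromosome. Of 23 chromosomes, 12 had a median outside the central 95% of random gene sets of the same size matched on expression. Chromosome 20 had the highest median, 0.94 over 399 measured genes, followed by chromosomes 2 (0.62 over 961) and 16 (0.40 over 659). The lowest were X (-0.97 over 519 genes), where AMOT, PLS3 and IRS4 lie, and 22 (-0.38 over 351). Chromosomes 13, 18, 6 and 17 had medians of 0.32, 0.30, 0.21 and 0.21, and chromosomes 1, 12 and 5 of -0.20, -0.08 and -0.07. At a minimum of 10 CPM the medians of chromosomes 12 and 5, among others, turned positive, at 0.01 and 0.06. DNA copy number was not measured here. The common shift of -0.54 with total counts exceeded every positive median except those of chromosomes 2 and 20.

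**Figure D4:**
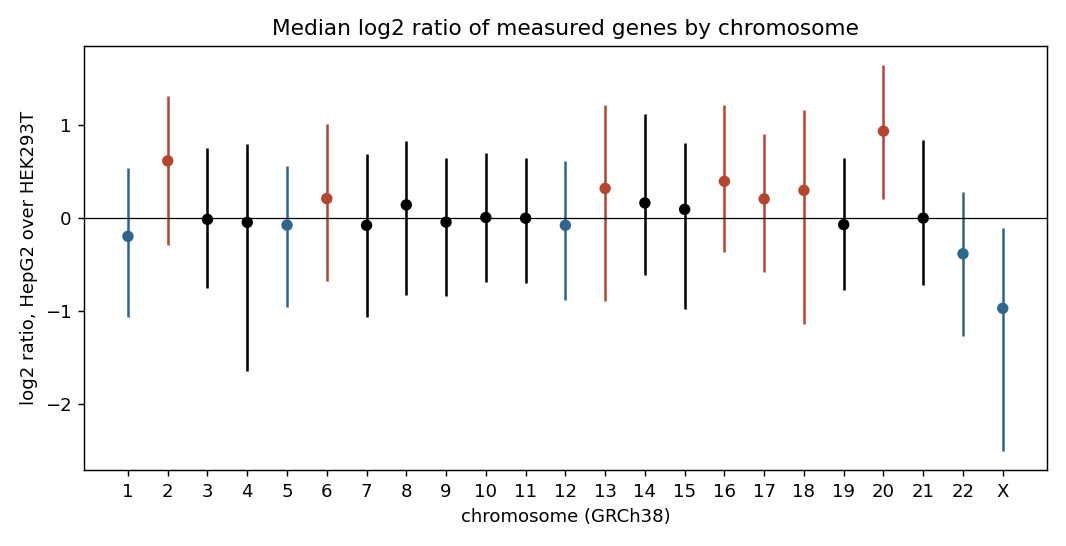
Median log2 ratio of HepG2 over HEK293T (points) and its quartiles (vertical lines) for measured genes on each chromosome, on the vertical axis, by chromosome on the horizontal axis. Red and blue mark medians above the 97.5th or below the 2.5th percentile of random gene sets matched on expression, with chromosome 20 highest at 0.94 and X lowest at -0.97.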

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

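The totals without the 100 most abundant genes, the protein-coding set and the floor of 10 counts were chosen after the data were seen, and the other settings before. The largest scaling shift, -0.54 on the log2 scale, was too small to turn any gene at least 4-fold apart. No named gene at least 4-fold apart and no list outside the central 95% of random lists changed direction, with 1 exception. The median of endothelial markers, 2.28, was -4.10 at a minimum of 10 CPM and -0.74 with no filter beyond 1 count. It was 0.23 with total counts, 0.56 with upper quartile factors and 0.71 with thinning. All these settings change which markers are measured, and over the same 7 markers total counts gave 1.74. Those of immune cell markers and of oncofetal and imprinted genes, 3.65 and 3.8, fell to 0.087 and 0.96 with no filter, and that of immune cell markers to 1.69 with totals that leave out the 100 most abundant genes, which also changes the markers measured. With no filter the medians also moved by more than 1.5-fold for drug-metabolising enzymes (6.35 to 3.27), embryonic kidney factors (-7.41 to -4.31), neuronal genes (-3.86 to -2.29), complement and acute phase genes (7.89 to 6.13), bile acid genes (4.88 to 4.09), gluconeogenesis and amino acid genes (3.32 to 2.22), epithelial genes (3.41 to 2.32), NF-kB targets (2.40 to 1.36) and erythroid markers (-1.65 to -0.29). At 10 CPM they were -6.85 for neuronal genes, 7.07 for drug-metabolising enzymes, -8.65 for embryonic kidney factors, 10.30 for complement and acute phase genes, 5.61 for bile acid genes, 5.33 for epithelial genes, 1.75 for NF-kB targets, 0.22 for erythroid markers and 4.60 for immune cell markers. The minimum of 10 CPM also moved adrenal cortex genes (2.49 to 5.90), interferon-stimulated genes (1.17 to 2.31), Wnt targets (1.67 to 2.75) and immediate early genes (0.53 to 1.13). With 5 counts added medians were -5.61 for HOX genes, -4.47 for embryonic kidney factors, 10.97 for plasma proteins and 5.07 for drug-metabolising enzymes. Total counts gave 4.01 for bile acid genes, -6.38 for embryonic kidney factors, 2.32 for immune cell markers and 0.59 for interferon-stimulated genes, and totals without the 100 most abundant genes -4.74 for embryonic kidney factors and 2.31 for gluconeogenesis and amino acid genes, where measured members changed as well. Counts of genes at least 4-fold higher (1670 in the HepG2 and 2241 in the HEK293T library) stayed within 1.5 times under each scaling, thinning, added count and the interval rule. They were 1092 and 968 at 10 CPM, and 4434 in the HEK293T library with no filter. All 1265 HepG2 genes called with total counts and 2241 of the 2813 HEK293T genes were also called with TMM scaling. Total counts move all ratios the same way, so this nesting follows from the scale and is no separate support for the calls. Genes present in the HepG2 library alone numbered 114 at 10 CPM, 1072 with no filter and 520 with a floor of 10 counts, against 293. Those in the HEK293T library alone numbered 249, 2718 and 1268, against 842. These minimums change which genes can count. With the 100 most abundant genes of either library left out, small RNA genes held 0.30% of HepG2 and 0.405% of HEK293T counts, ribosomal protein genes 3.13% and 2.83%, and histones 0.963% and 1.53%, since most of the first 2 classes' counts lie in those abundant genes. The same removal from the scaling totals shifted the median of all genes by -0.39, against -0.54 with total counts, and turned the medians of the cytidine deaminase, G2 and M phase, nucleic acid sensing, cholesterol and housekeeping lists negative, as total counts did. The number of lists above the 97.5th percentile was 18 to 20, and 6 lay below the 2.5th percentile in each setting. Chromosomes outside the central 95% numbered 12, and 13 at 10 CPM, where the medians of chromosomes 3, 4, 5, 7, 9, 11, 12 and 19 turned from negative to positive. Under all alternatives together, 529 values of named genes left their counting interval and 1298 stayed within it. Of the list medians, 138 left theirs, another 2, both of endothelial markers, changed direction, and 184 stayed within it. No paired analysis was possible because each line had a single library and the lines shared no more than replicate number 1, and leaving out a library was not possible for the same reason. Depth limits genes under about 0.05 CPM, where a count of 0 allows up to 3 counts.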

Other observations

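The genes and gene groups of this and the next paragraph, and the tests of the globin gene cluster, of a fixed HBB and HBD ratio, of plasmid sequence, of depth and of chromosome copy number were chosen after the data were seen; the other tests were written before. Among 196 symbol stems with at least 10 measured genes, those with the lowest medians apart from HOX stems were NKX homeobox genes (-6.61) and synaptotagmins, SYT, which are calcium sensors of vesicle release (-6.26). They were followed by the secreted ADAMTS proteases (-5.20). Collagen genes, COL, had a median of -3.26 over 32 genes and the Wnt receptor genes FZD -3.25 over 11. At the other end stood the claudins, CLDN, which form tight junctions, with a median of 4.61 and 7 of 10 genes at least 4-fold higher in the HepG2 library. TNF receptor genes, TNFRSF, had a median of 2.35, with 6 of 10 genes at least 4-fold higher in the HepG2 library.

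Some differences covered neighbouring genes. Runs of at least 4 adjacent measured genes with at most 3 counts in the HepG2 library included 6 genes of the HOXD cluster on chromosome 2 (176092891 to 176137098) and 6 on X (152133310 to 152737669) that include the cancer-testis genes MAGEA3, MAGEA10 and MAGEA12. In the HEK293T library such a run covered 8 genes on chromosome 15 (24985053 to 25101666), all but PWAR5 SNORD116 copies of the imprinted Prader-Willi region. How reads were divided among these copies is uncertain, so they are not separate cases. Another run covered 4 genes on chromosome 4 (68815993 to 69214731) with the glucuronosyltransferase genes UGT2B7 and UGT2B10. INSIG1, with 5 and 8624 counts, stood beside EN2 and CNPY1, with 2 and 2234 counts and 0 and 249 counts, while RBM33 on the same arm had 2716 and 3739 counts. Its paralog INSIG2 had 8630 and 836 counts, 11-fold (10.2 to 11.8) higher in the HepG2 library. GSTP1, a glutathione transferase, had 1 and 13231 counts, a ratio of 12451-fold (2234 to 491823).

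HBB and the neighbouring delta-globin gene HBD had 80125 and 73273 counts and 152881 and 89451 counts, together 0.357% of HepG2 counts and 0.342% of HEK293T counts. Erythroid gene expression is argued against by other erythroid markers, of which 1 of 9, TAL1, reached 1 CPM in either library. Activation of the gene cluster as a whole is argued against by HBG1, HBG2 and HBE1, whose highest count was 0.0562% of the HBB count. These counts cannot decide on activation of HBB and HBD alone, which would leave the other genes of the cluster low. The HBD to HBB ratio was 1.91 in HepG2 and 1.22 in HEK293T, 1.56 times apart (1.54 to 1.58, counting error only). That interval leaves out 1, which a fixed ratio would give if counting were the only error. A single source dividing in a fixed ratio still stays open, since 1 library per line gives no spread between libraries to compare this with. Globin sequence on the transfected plasmid could give such counts and stays open at 0.357% of HepG2 counts, since plasmid sequence and reads were not used here; other biological sources were not tested.

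The HEK293T library had 2.87 times as many genes present in it alone as the HepG2 library, 842 against 293. Depth is argued against by the total counts, 1.37 times as many in the HepG2 library, where more genes were at the floor. After TMM scaling its floor was the slightly higher, at 0.0555 against 0.0522 CPM, yet thinning it to 0.729 of its counts raised the 842 genes to no more than 963. Carry-over of HepG2 reads into the HEK293T library, which could hide HepG2 genes, was bounded at 0.00214% by the upper limit of the 4 AFP counts there. Subtracting that share left 300 genes present in the HepG2 library alone against 842, a ratio of 0.356. A difference between the lines, their media or their reagents stays open and untested.

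Genes on chromosome 20 had a median log2 ratio of 0.94 towards HepG2, against 0.02 for other chromosomes. A few strongly different genes could hardly move a median over 399 genes, so they were an unlikely cause before any test. The 25th percentile lay 1.10 above that of the other chromosomes, so the shift was not limited to a few genes. GC content and transcript length are argued against by centring within 20 bins of each, which left a median of 0.90. A higher copy number of chromosome 20 in HepG2 than in HEK293T may account for the median of 0.94 and stays open, since DNA was not measured here and the line and any such gain cannot be told apart.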
